A study of Mus musculus with 12 samples.

How the data were processed

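Total RNA of whole mouse spinal cord had been sequenced in 12 libraries, with 3 libraries in each of 4 groups. Mice lacking the dopamine receptor gene Drd2 conditionally (labelled Drd2mGFAP cKO, called cKO here) and littermate controls (labelled wt) were compared without disease (basal) and at day 17 of experimental autoimmune encephalomyelitis (EAE). The series calls that time the peak of EAE. The mice were C57BL/6 and 2 to 3 months old, and the RNA was taken up in Trizol, per the labels' protocols. Each library was labelled as a separate biological replicate.

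The deposited table held raw read counts per gene, 54532 genes in all, with the symbol, chromosome, start, end, length and biotype of each. Reads had been aligned with HISAT2 2.0.5 to the mouse genome build mm10 and counted with featureCounts 1.5.0-p3, per the submitters' processing notes. The strand setting, the treatment of reads that map to several places, the annotation release, the sequencing run and the library kit were not given in the sources used here. Counts of overlapping, antisense or near-identical genes (such as Tgtp1 and Tgtp2, or Hba-a1 and Hba-a2) are therefore uncertain. Of the gene identifiers, 54409 were found in GENCODE M21, 53842 of them with the same symbol, and all 482 symbols of the gene lists were found in the table. Gene names, identifiers and coordinates were taken from the deposited table. No genome sequence was used here.

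Library totals ran from 15128913 to 17592105 counts, and 19860 genes had 0 counts in every library. At that depth 1 count was worth less than 0.1 CPM, so that low genes were limited by counting error as well as by the spread between mice. Where a group had 0 counts of a gene, a fold was computed against a floor of 3 counts over the group and written as a lower bound. With 1 to 3 counts the ratio was given with its exact Poisson interval (95%), taking the count of the other group as fixed. Both cover counting error only. Levels are given as TMM-normalised CPM, mean ± SD over the 3 libraries of a group, except where CPM of the library total is named.

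The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the deposited counts, with TMM factors, the filter for low counts that edgeR offers, no robust option, and no covariate besides the group. Both EAE responses and the difference between them came from 1 fit of all 12 libraries. The cKO and control libraries were compared within the 6 EAE and within the 6 basal libraries, so that the spread of the other condition did not enter. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05, and the SE of a log2 fold change was its size divided by the square root of F. These choices, the gene lists and the alternatives were fixed before the data were examined, except where a choice is said to have been made later.

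Genes were named by a rule. It took Drd2, then up to 10 genes with the largest rise and 10 with the largest fall in each comparison among those that passed, had a mean of at least 1 CPM in a group and had all 3 libraries of 1 group above those of the other. Where fewer than 5 passed, the 5 with the smallest p were added. Up to 4 members of each list described for a comparison were taken by smallest p, and Rgs5, Cryab, Tnf, Il6, Ccl2 and Gfap were fixed for every comparison. Predicted genes, unnamed transcripts and antigen receptor segments were left out.

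There were 38 lists, written from general knowledge. They covered astrocyte markers, pan-reactive, A1 and A2 astrocyte genes, homeostatic microglia, activated microglia and macrophages, T cells, B and plasma cells, monocytes and infiltrating macrophages, neutrophils, dendritic cells, chemokines, inflammatory cytokines, the NF-kB, type I interferon and interferon gamma responses, MHC class I and II, complement, myelin and mature oligodendrocytes, oligodendrocyte precursors, cholesterol synthesis, neurons, motor neurons, sensory neurons, endothelium, pericytes and smooth muscle, fibroblasts and meninges, Schwann cells, skeletal muscle, erythrocytes, ependymal cells, proliferation, immediate early genes, dopamine signalling and heat shock. Sex-linked and mitochondrially encoded genes were 2 check lists outside the count. The lists share some genes, as Gfap, Iigp1, Serping1, Ciita, Itgax and Egr2 each stood in more than 1. A list with at least 5 tested members was tested with camera at a preset correlation of 0.01, adjusted over the lists of the comparison. Camera with an estimated correlation and fry were run as alternatives.

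The other alternatives were DESeq2's size factors, no filter on low counts, the replicate number as a block, limma voom with sample weights, DESeq2's Wald test (DESeq2 1.42.0), other sets of libraries in the fit, a minimum of a 2-fold change, and leaving out each library in turn. Leaving out libraries that stood apart was added after the data were seen. The replicate numbers did not mark shared animals, litters or days in the labels. A covariate for sex was planned and could not be estimated, because every basal library carried Xist RNA and every EAE library Y-linked RNA.

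The steps were tested on simulated data with the real library sizes, 1 mean per gene over all groups, and 200 genes changed. The changed genes had a mean of at least 1 CPM. The spread was that fitted to the real libraries, those that stood apart included. Where more genes change in the data than were planted, the recovery need not carry over. For EAE against basal in control mice edgeR recovered 3% of 2-fold and 49% of 4-fold changes, with 2 false calls. The values were 2% and 34% for the same contrast in cKO mice, and 32% and 81% for cKO against control at EAE, with 5 false calls. For cKO against control at basal and for the difference of responses edgeR recovered 0% at either size. DESeq2 recovered 51% and 41% of the 4-fold changes there, with 54 and 24 false calls. Principal components were taken over the 500 most variable genes (log2 CPM with a prior count of 2). Response shares and list levels per library used log2 of CPM plus 0.5. Figures were drawn with matplotlib 3.10.9, and counting intervals used scipy 1.17.1 under Python 3.11.15.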

Results

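Gene expression in the spinal cord was measured by RNA sequencing in mice with a conditional deletion of Drd2, the gene of the dopamine D2 receptor, and in littermate controls. The cKO label names the GFAP promoter, which is active in astrocytes. Both genotypes were sampled without disease and during EAE, an immune attack on myelin induced by immunization that serves as a model of multiple sclerosis. There were 3 mice in each of the 4 groups (control basal, cKO basal, control EAE and cKO EAE), and the libraries held 15128913 to 17592105 counts each. According to the series title, the study asked whether astrocytic DRD2 affects inflammation of the central nervous system.

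Drd2 (ENSMUSG00000032259, chromosome 9, 49340627 to 49408177, plus strand, build mm10) was counted in every library. Its TMM-normalised level in CPM was 21.9 ± 4.02 in control basal, 28.5 ± 9.49 in cKO basal, 9.15 ± 0.396 in control EAE and 12.8 ± 6.33 in cKO EAE (SD, n = 3 each). Scaled to library totals alone, the levels were 22.4, 26.3, 9.43 and 13.2 in the same order. The level was not lower in cKO than in control mice at either state. The log2 fold change was 0.40 (SE 0.34) at basal and 0.52 (SE 0.35) at EAE, with adjusted p of 0.997 and 0.318 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The value at EAE moved with single libraries (6.72, 12.4 and 19.4 CPM in cKO EAE 1, 2 and 3), to 0.0978 without cKO EAE 3 and 0.83 without cKO EAE 1. Whole spinal cord holds other cells that express Drd2, and the deleted part of the gene was not given in the sources used here. The gene count therefore does not test a deletion in 1 cell type, and the genotype stands as labelled. Between basal and EAE the receptor RNA fell in control mice, with a log2 fold change of -1.25 (SE 0.37) and adjusted p = 0.041. The change in cKO mice was -1.15 (SE 0.37) with adjusted p = 0.17 by the same test, and the difference between both changes was 0.10 (SE 0.52).

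RNA of sex-linked genes separated the states in both genotypes. Xist, which is transcribed from the inactive X chromosome of females, was at 473 ± 141 CPM in control basal and 579 ± 165 in cKO basal, and at or below 0.292 CPM of the library total in every EAE library. The Y-linked gene Ddx3y had 0 counts in all 6 basal libraries and 70.3 to 77.0 CPM of the library total in the 6 EAE libraries. The basal libraries thus carried female RNA and the EAE libraries male RNA. Every contrast of EAE with basal is also a contrast of sex, and cKO and control were compared within 1 sex.

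A pair of libraries stood apart from their groups. In cKO basal 2, 17220 genes were detected, against 24303 to 26056 in the 11 other libraries. Ribosomal protein genes took 6.79% of its counts (0.913 to 1.94% elsewhere) and mitochondrially encoded mRNAs 1.19% (4.10 to 6.56% elsewhere). In that library 19.8% of genes lay over 4-fold from the control basal mean, against 0.00823 and 0.0247% in the other cKO basal libraries, and short genes were raised over long ones. A smaller shift between short and long genes was seen in control basal 1. The library cKO EAE 3 carried little of the EAE response. Its Cd74 level was 6.84 CPM of the library total, against 345 to 2759 in the other 5 EAE libraries and 0.727 to 3.18 in the basal libraries. On the first principal component (89.5% of variance) it lay at -32.0, between the basal libraries (-69.2 to -44.2) and the other EAE libraries (43.4 to 83.2).

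**Figure D1:**
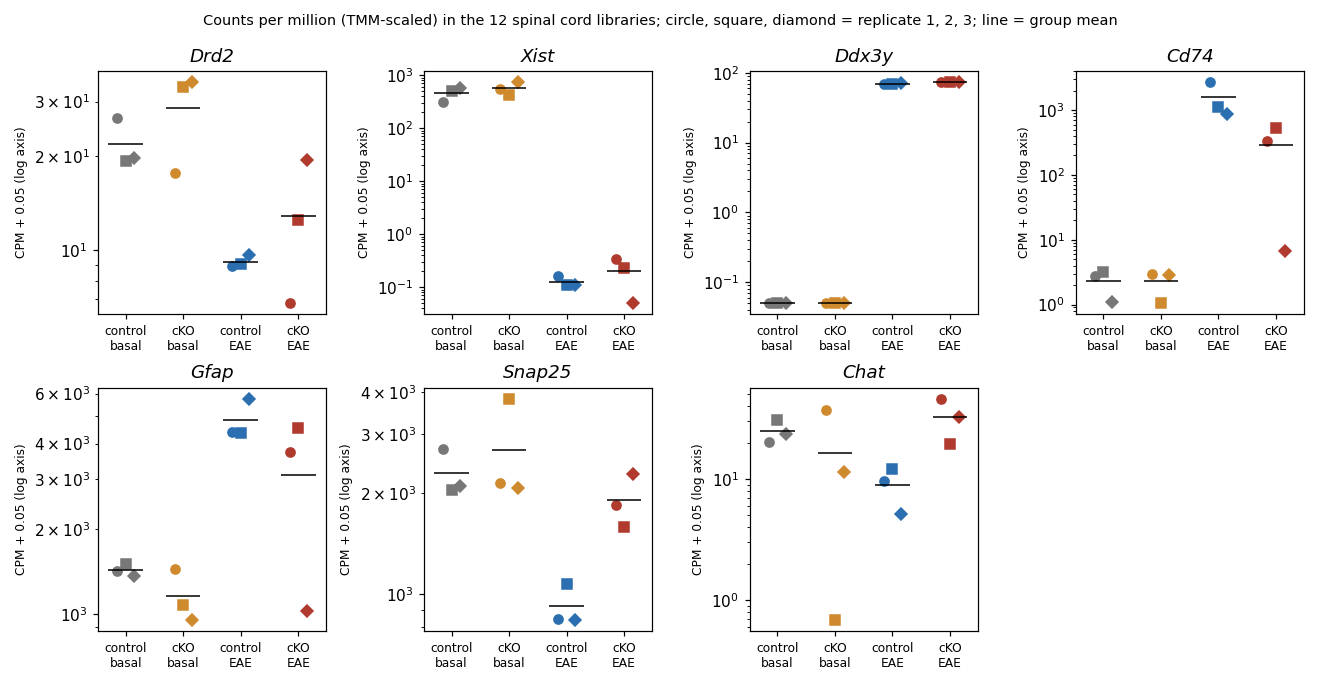
TMM-normalised CPM (plus 0.05, log axis) of 7 genes in each of the 12 libraries, with circles, squares and diamonds for replicates 1, 2 and 3 and a line at each group mean. Drd2 shows no lower level in cKO, Xist and Ddx3y split basal from EAE libraries, Cd74 and Gfap in cKO EAE 3 lie near the basal libraries, and the group means of Snap25 and Chat are lowest in control EAE.

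The first comparison asked what EAE changed in the spinal cord of control mice. Genes of infiltrating leukocytes, antigen presentation and inflammatory signalling rose, reactive astrocyte genes rose, and 8 of 16 neuronal and 3 of 15 myelin genes fell. With all 12 libraries no list call of this comparison held with an estimated correlation (adjusted p = 0.0926 for the neuronal and 0.166 for the myelin list). All 16 T cell genes rose, among them Zap70, a kinase of the T cell receptor (log2 fold change 2.93, SE 0.40), and Trac, the receptor's alpha chain (3.17, SE 0.52). All 12 monocyte and macrophage genes rose, such as lysozyme Lyz2, from 7.60 ± 3.47 to 2047 ± 1181 CPM, and fibronectin Fn1, from 47.0 ± 17.7 to 1798 ± 76.5 CPM. Counting 18601 tested genes, 3183 changed at an adjusted p below 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2243 upward and 940 downward, and 2388 of them by at least 2-fold.

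By fitted log2 fold change the largest rises were those of F10, Mmp12, Clec4e, Wfdc17, Selp, Il18r1 and Il1rn, with the Y-linked genes Ddx3y, Kdm5d and Uty among them. For genes with 0 basal counts the fitted value depends on the prior count, so the order of genes is not settled. Cst7, outside these 10, rose by a ratio of 3214 (interval 577 to 126940 from 1 basal count). F10, a coagulation factor that macrophages express, was at least 1386-fold higher than a floor of 3 counts over the control basal group. The same bound was at least 744-fold for the macrophage elastase Mmp12, at least 365-fold for Wfdc17, at least 363-fold for the endothelial selectin Selp and at least 355-fold for Il18r1, a subunit of the interleukin 18 receptor. Clec4e, an innate immune receptor, rose by a ratio of 4242 (interval 761 to 167543 from 1 basal count) and the interleukin 1 receptor antagonist Il1rn by 3500 (628 to 138243). Among the falls were Xist, Myoc (-3.80, SE 0.61), the GABA receptor subunit Gabrr2 (-3.03, SE 0.61), Arl4d (-2.96, SE 0.48), Kirrel2 (-2.66, SE 0.39) and the prostaglandin synthase Ptgds (-2.58, SE 0.59). Chrna2, a nicotinic receptor subunit, Uts2, Aqp6 and the neuropeptide gene Calca fell by -2.55, -2.44, -2.25 and -2.21 on the log2 scale. Their adjusted p ran from 4.15e-05 (Xist) to 0.0182 (Calca) by the same test.

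Antigen presentation and interferon lists moved together. All 10 MHC class II genes rose (median log2 fold change 5.11), with Cd74, the invariant chain, going from 2.29 ± 1.09 to 1582 ± 1004 CPM and H2-Ab1 by 9.45 (SE 1.32). In MHC class I 14 of 15 genes rose (median 5.05). All 20 interferon gamma response genes rose (6.04), such as the GTPases Gbp4 (6.12, SE 0.76) and Iigp1 (8.17, SE 1.16), and all 20 type I interferon genes (4.34), such as Irf7 (5.57, SE 0.95). Complement rose in 14 of 15 genes (4.76), with its inhibitor Serping1 at 5.15 (SE 0.61). Of the chemokines 17 of 19 rose, with a median of 6.23, or 6.08 with genes at 0 in the basal group set to their bound. Of the cytokines 12 of 13 rose, with a median of 5.62, or 5.03 with such bounds. Ccl2, which recruits monocytes, went from 0.0791 ± 0.0690 to 41.5 ± 9.03 CPM. Tnf rose by a ratio of 347 (95.9 to 2862 from 2 basal counts), and Il6 by 5.13 (SE 1.39). All 16 NF-kB response genes rose (2.87), among them the adhesion molecules Icam1 (5.79, SE 0.77) and Vcam1 (2.42, SE 0.34). Each of these lists passed camera, with adjusted p = 0.0926 with an estimated correlation.

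Reactive glial and dividing cell genes rose as well. In the pan-reactive astrocyte list 12 of 13 genes rose (median 4.09), with lipocalin Lcn2 from 1.79 ± 1.42 to 707 ± 73.4 CPM and Gfap, the intermediate filament of astrocytes, from 1429 ± 69.7 to 4835 ± 802 CPM (log2 1.76, SE 0.44). In the A1 list 8 of 11 rose (4.32) and in the A2 list 8 of 12 (3.12), including Ptgs2 and Cd14. Activated microglia and macrophage genes rose in 14 of 16 cases (2.98), and proliferation genes in 11 of 12 (4.39), such as Mki67 (6.26, SE 0.92). The adjusted p of these lists and of the T cell and monocyte lists was also 0.0926 with an estimated correlation. Homeostatic microglia genes rose in 8 of 12 cases (2.40), such as Csf1r and Tmem119, fibroblast and meningeal genes in 6 of 10 (1.83), such as Col1a1, neutrophil genes in 3 of 11 (3.29) and immediate early genes in 5 of 12 (0.75). These 4 lists passed camera, with adjusted p = 0.128 with an estimated correlation. Dendritic cell genes rose in 5 of 8 cases (4.26), with adjusted p = 0.141 with an estimated correlation. The astrocyte marker list was not called (camera adjusted p = 0.102) while 3 of its 18 genes rose and 5 fell. Sox9 rose by 0.99 (SE 0.21), and the connexin Gjb6, Cldn10 and Ntsr2 fell by -1.22, -1.36 and -1.51.

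Neuronal, myelin and dopamine lists went down relative to the other RNA of whole spinal cord. Here and between genotypes, such levels do not separate expression per cell from the mix of cells. Of 16 neuronal genes 8 fell (11 adjusted over the list alone), with a median of -1.18. The vesicular GABA transporter Slc32a1 fell by -1.18 (SE 0.17), the neurofilament Nefl by -1.40 (SE 0.28) and the synaptic protein Snap25 by -1.31 (SE 0.28). The list's adjusted p was 0.0926 with an estimated correlation. Of 10 motor neuron genes 3 fell (8 adjusted over the list alone), among them the choline transporter Slc5a7 (-2.08, SE 0.50), with adjusted p = 0.149 with an estimated correlation. In the myelin list 3 of 15 fell, such as Mbp (-0.91, SE 0.27) and Tspan2 (-0.54, SE 0.16), with adjusted p = 0.166 with an estimated correlation. In the dopamine list 2 of 10 fell, Drd2 and Ppp1r1b (DARPP-32, a target of dopamine signalling), with adjusted p = 0.153 with an estimated correlation, and in the heat shock list 1 of 10 fell, with 0.226. Of the remaining lists none was called. Their median log2 changes were 0.49 for endothelium, 0.54 for pericytes, 0.59 for Schwann cells, 0.20 for oligodendrocyte precursors, -0.12 for cholesterol synthesis, -1.30 for sensory neurons, 1.17 for B and plasma cells, -0.16 for skeletal muscle, -2.18 for erythrocytes and 0.05 for ependymal cells. The 13 mitochondrially encoded mRNAs, kept as a check, had a median of 0.07, and of 5 sex-linked genes 4 rose and 1 fell. Rgs5 (0.29, SE 0.43) and Cryab (-0.76, SE 0.40) did not pass, with adjusted p of 0.742 and 0.248 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

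By camera 25 of 36 lists changed in control mice, 20 upward and 5 downward, against 0 with an estimated correlation and 29 by fry. The number of genes depended on each library, with 1936, 1752 and 1724 genes without control basal 1, 2 and 3 and 1833, 2073 and 1767 without control EAE 1, 2 and 3. Leaving out cKO basal 2 and cKO EAE 3, which share the fit, gave 8673 genes, a choice made after the data were seen. Of the 36 lists 17 then passed with an estimated correlation, among them T cells and the interferon gamma response (adjusted p = 0.0267 each) and neurons (0.0448). In that fit 16 of 16 neuronal, 10 of 10 motor neuron and 13 of 15 myelin genes fell. The motor neuron and myelin lists did not pass with an estimated correlation (adjusted p of 0.352 and 0.301).

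The second comparison asked the same of cKO mice. Few single genes passed, and inflammatory lists rose as groups by camera with its preset correlation. None of them passed with an estimated correlation (smallest adjusted p = 0.206). At an adjusted p below 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7 of 18601 genes changed. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty rose and Xist fell, as the sexes of the groups differ. The other 2 were Lrg1, a glycoprotein induced in inflammation, which rose from 0.902 ± 0.652 to 26.4 ± 14.3 CPM (log2 4.81, SE 0.66, adjusted p = 0.0439), and Ptgs2, the inducible cyclooxygenase, which rose from 0.775 ± 0.270 to 13.9 ± 8.58 CPM (4.17, SE 0.57, adjusted p = 0.0439). An unadjusted p below 0.05 was reached by 3643 genes. DESeq2 called 1239, and limma voom with sample weights 3648.

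Camera called 23 of 36 lists, 21 upward and 2 downward. Members seldom passed over all genes but did when adjusted over the list alone. That count was 20 of 20 interferon gamma genes (median 4.05), 12 of 12 monocyte genes (5.40), 14 of 16 T cell genes (4.24, or 4.13 with genes at 0 set to their bound), 9 of 10 MHC class II genes (4.18), 17 of 19 chemokines, 12 of 13 pan-reactive astrocyte genes (2.57) and 13 of 16 NF-kB genes (1.62). Cd74 went from 2.23 ± 1.07 to 292 ± 265 CPM (adjusted p = 0.0726), Lyz2 from 6.69 ± 2.37 to 346 ± 323, Lcn2 from 2.35 ± 1.31 to 112 ± 98.8 and Gfap from 1159 ± 254 to 3101 ± 1842 (1.42, SE 0.44, adjusted p = 0.157), by the same test. Tnf was at least 41.9-fold above its floor with an adjusted p of 0.111, Il6 at least 8.70-fold with 0.207, and Ccl2 was at 6.92 (SE 1.34) with 0.0726. The adjusted p of these lists was 0.206 to 0.215 with an estimated correlation. Fry called 16 lists.

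Lists of non-immune cells differed in direction. Fibroblast and meningeal genes passed camera (6 of 10 up adjusted over the list alone, median 1.79), as did endothelium (4 of 12, 0.61), pericytes and smooth muscle (2 of 10, 0.71) and Schwann cells (6 of 9, 2.30), each with adjusted p = 0.206 with an estimated correlation. The Schwann cell list lay above the mean of cKO basal 1 and 3 (cKO basal 2 left out after the data were seen) by 1.96, 0.81 and 1.21 (mean log2) in cKO EAE 1, 2 and 3. Neuronal genes passed camera downward (median -0.16, none of 16 changed singly) with adjusted p = 0.256 with an estimated correlation, and heat shock genes with 0.215. Motor neuron (0.52), myelin (-0.03) and astrocyte marker (0.13) lists were not called.

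In cKO mice the calls depended on which libraries were fitted. Those of Lrg1 and Ptgs2 were lost without cKO basal 1, cKO basal 3, cKO EAE 1 or cKO EAE 2 (5 genes each), and that of Ptgs2 also without cKO basal 2. Without cKO EAE 3 the number of genes was 1075, and without both cKO basal 2 and cKO EAE 3, a choice made after the data were seen, it was 2715 (2049 up and 666 down). In that smaller set all 16 T cell, 12 monocyte, 20 interferon gamma, 15 MHC class I and 10 MHC class II genes rose, and the interferon gamma list had an adjusted p of 0.00893 with an estimated correlation, against 0.206 with all libraries, and 17 of 36 lists passed that way. Of 16 neuronal genes 6 fell there, while of the 15 myelin genes 1 rose and 0 of 10 motor neuron genes changed. A fit of the 6 cKO libraries alone called 0 genes by edgeR, with 860 at an unadjusted p below 0.05.

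The third comparison asked how cKO mice differed from control mice at EAE. In it, genes said to rise or fall were higher or lower in cKO than in control mice. Neuronal and motor neuron genes were higher in cKO, some myelin and astrocyte genes were higher, and inflammatory lists were lower as groups by camera with its preset correlation. Of 35 lists 0 passed by fry or with an estimated correlation (adjusted p of 0.498 to 0.522 for the inflammatory lists). Among the genes higher in cKO were acetylcholine genes of motor neurons. In control and cKO EAE Slc5a7 was at 19.0 ± 6.52 and 96.4 ± 34.7 CPM (log2 2.39, SE 0.37, adjusted p = 0.044). Chat, which makes acetylcholine, was at 8.90 ± 3.57 and 32.6 ± 13.4 (1.92, SE 0.42, adjusted p = 0.0482). Slc18a3, which loads it into vesicles, was at 21.7 ± 7.03 and 78.9 ± 28.5 (1.90, SE 0.35, adjusted p = 0.044). Such genes also varied between mice without disease. Chat had 636, 7 and 191 counts in cKO basal 1, 2 and 3. It had 317 to 552 in control basal and 87 to 205 in control EAE. Chodl had 846, 382 and 170 in the same cKO libraries. It had 540 to 724 in control basal and 72 to 214 in control EAE. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1374 of 17914 genes differed, 1099 higher and 275 lower in cKO, 305 of them by at least 2-fold. The smallest adjusted p was 0.044, and in each of these genes the 3 cKO libraries lay on 1 side of the 3 control libraries, which chance gives in 10% of genes and which held for 48.0% of all tested genes.

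The other genes with the largest rise were Isl2 (2.55, SE 0.49), a transcription factor of motor neurons, Chrna2 (2.53, SE 0.38), Chodl (2.15, SE 0.45), Aqp6 (2.05, SE 0.45), the potassium channel Kcnj14 (1.98, SE 0.36), Calcb (1.97, SE 0.37) and Gli1 (1.96, SE 0.45), an effector of hedgehog signalling. Asb11 (-3.18, SE 0.64), Bdkrb1 (-3.13, SE 0.66), a bradykinin receptor, Clec1b (-2.49, SE 0.44), S100a4 (-2.47, SE 0.55) and Guca1a (-2.39, SE 0.40) fell the most. They were followed by the serotonin receptor Htr2b (-2.27, SE 0.32), the prostaglandin receptor Ptger2 (-2.23, SE 0.45), the cytokines Tnfsf14 (-2.21, SE 0.47) and Lta (-2.17, SE 0.47), and Fpr1, a receptor of myeloid cells for bacterial peptides, from 8.35 ± 2.14 to 1.83 ± 0.90 CPM (-2.15, SE 0.42). Their adjusted p ran from 0.044 to 0.0493 by the same test.

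Of 16 neuronal genes 9 rose (13 adjusted over the list alone, median 0.80), among them the glycine transporter Slc6a5 (1.17, SE 0.14), Slc32a1 (0.89, SE 0.13), Snap25 (1.09, SE 0.19) and Nefl, from 545 ± 91.0 to 1263 ± 242 CPM. Of 10 motor neuron genes 6 rose (10 adjusted over the list alone, median 1.65), including Slit3 (1.15, SE 0.18) and Isl1 (1.41, SE 0.30). Of 15 myelin genes 3 rose, Aspa (0.74, SE 0.14), Ugt8a (0.68, SE 0.14) and Fa2h (0.73, SE 0.16), and 12 did so adjusted over the list alone (median 0.54). Of 18 astrocyte markers 5 rose (0.33), with Ntsr2 at 1.26 (SE 0.17), Gjb6 at 0.87 (SE 0.13), Fgfr3 at 0.83 (SE 0.14) and Cldn10 at 0.93 (SE 0.15). Each of these lists passed camera, with adjusted p = 0.498 with an estimated correlation. Erythrocyte genes passed upward (1 of 6, Hbb-bt at 1.43, SE 0.32), also with 0.498. Schwann cell genes did so with 0 of 8 changed singly (median 0.97) and cholesterol synthesis genes with 0 of 21 (0.26), at adjusted p of 0.522 and 0.713 with an estimated correlation. Prx, a Schwann cell gene, was at 22.7 ± 20.8 CPM in cKO EAE and 2.08 ± 0.380 in control EAE.

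Inflammatory lists passed camera downward with few members changed singly. Of 16 T cell genes 1 fell, Zap70 (-1.67, SE 0.35, adjusted p = 0.0474 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with a list median of -1.80. None of 12 monocyte genes (-2.57), 20 interferon gamma genes (-2.12), 10 MHC class II genes (-2.11), 15 MHC class I genes (-1.72), 15 complement genes (-1.73), 19 chemokines (-1.78), 13 pan-reactive genes (-1.51), 16 activated microglia genes (-1.42), 12 proliferation genes (-1.55) or 12 A2 genes (-1.11) passed singly. Of 16 NF-kB genes 0 passed over all genes and 15 fell adjusted over the list alone (-1.33), and of 13 cytokines (median -1.98) 1 fell, Lta. Of 12 immediate early genes 1 fell, Egr3 (-1.40, SE 0.30), and 7 did so adjusted over the list alone (-0.57). All of these had adjusted p = 0.498 with an estimated correlation. The A1 list was lower (-1.65) although its member Fbln5 rose (0.96, SE 0.19), with 0.513, and homeostatic microglia (-0.83) and type I interferon genes (-1.28) were lower with 0.522. Levels at EAE were wide in cKO: Lcn2 was at 112 ± 98.8 CPM against 707 ± 73.4 in control (-2.63, SE 0.77, adjusted p = 0.0715), Tnf at 2.55 ± 2.41 against 13.3 ± 3.72 (-2.34, SE 0.93, adjusted p = 0.126) and Gfap at 3101 ± 1842 against 4835 ± 802 (-0.61, SE 0.51, adjusted p = 0.42), by the same test. Il6 (-2.44), Ccl2 (-1.82), Rgs5 (0.34) and Cryab (-0.35) did not pass either, at 0.144, 0.208, 0.0842 and 0.146. Lists not called were dopamine signalling (median 0.29), endothelium (-0.06), fibroblasts and meninges (-0.15), neutrophils (0.10), dendritic cells (-1.22), B and plasma cells (0.20), oligodendrocyte precursors (-0.08), pericytes (0.12), skeletal muscle (0.28), ependymal cells (-0.14) and heat shock (0.13).

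By camera 24 of 35 lists differed at EAE, 7 higher and 17 lower in cKO. The number of gene calls depended on which library was left out. EdgeR called 0 genes without control EAE 1, 2 or 3 or cKO EAE 1. It called 3418 without cKO EAE 2 and 3336 without cKO EAE 3. The counts at an unadjusted p below 0.05 were 4201, 4933, 4623 and 4991 in the 4 fits with 0 calls. A fit of all 12 libraries also called 0 genes (2622 unadjusted), whereas DESeq2 called 4131 and limma voom with sample weights 5790 on the 6 libraries.

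Because cKO EAE 3 carried little of the response, the comparison was repeated without it, a choice made after the data were seen. Of the 3336 genes that then differed (1669 higher, 1667 lower), 1362 were among the 1374. All 12 monocyte (median -2.01), 20 interferon gamma (-1.57) and 15 MHC class I genes (-1.18) were lower in cKO. So were 13 of 16 T cell genes (-1.32), 7 of 10 MHC class II genes (-1.58), 15 of 16 NF-kB genes (-0.98) and 8 of 13 pan-reactive astrocyte genes (-1.03). Of the neuronal genes 13 of 16 were higher in cKO (0.69), of the motor neuron genes 9 of 10 (1.66) and of the myelin genes 12 of 15 (0.68). With an estimated correlation the adjusted p was 0.27 for these lists and 0.393 for MHC class II.

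**Figure D2:**
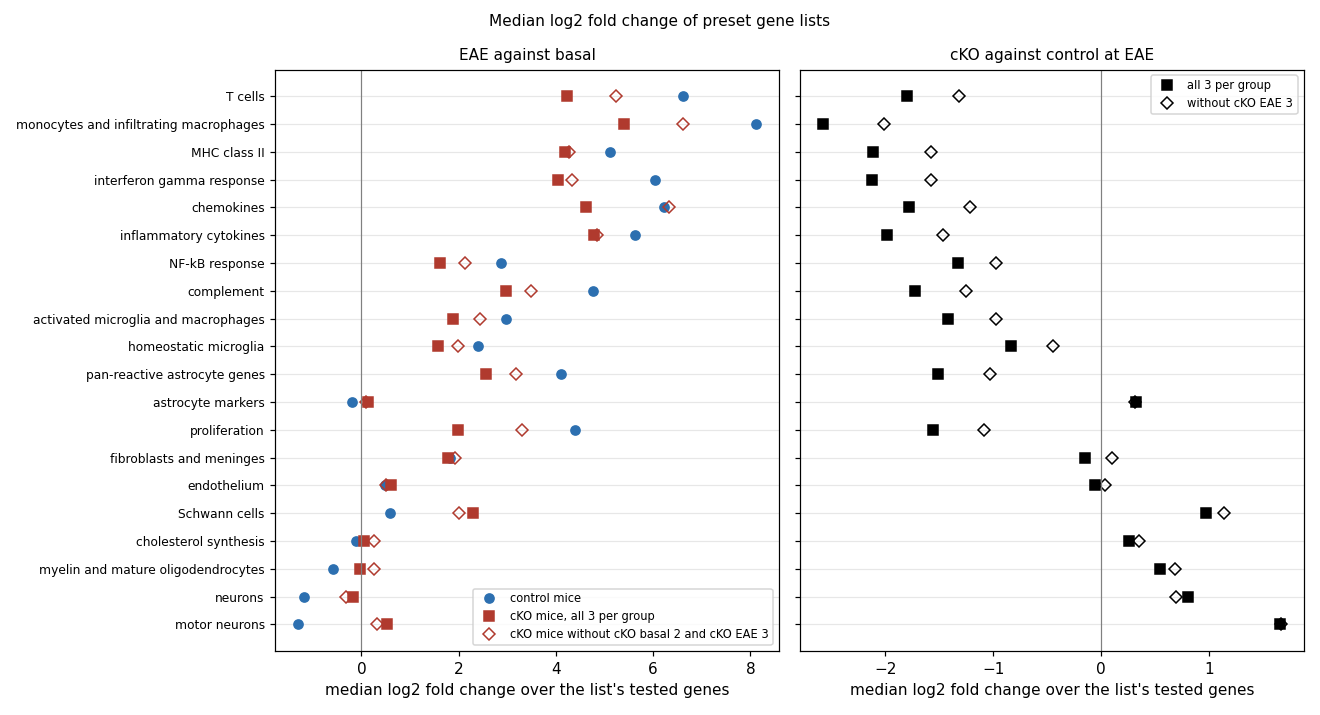
Median log2 fold change of 20 gene lists, on the left for EAE against basal in control mice (blue circles), in cKO mice (red squares) and in cKO mice without cKO basal 2 and cKO EAE 3 (open diamonds), and on the right for cKO against control at EAE with all libraries (black squares) and without cKO EAE 3 (open diamonds). The T cell list lies at 6.62 in control and 4.24 in cKO mice, and the motor neuron list at 1.65 on the right with all libraries and 1.66 without cKO EAE 3.

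The fourth comparison asked whether the genotypes differed without disease. No gene passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (0 of 17133, with 31 at an unadjusted p below 0.05). DESeq2 called 1 and limma voom with sample weights 0. Nearest to the threshold was Htr3a, a serotonin-gated channel, at 5.12 ± 1.37 CPM in control and 1.12 ± 0.279 in cKO (log2 -2.17, SE 0.41). Next came Zfp973 (2.24, SE 0.58), Pts, an enzyme of tetrahydrobiopterin synthesis, at 22.6 ± 6.05 against 11.2 ± 0.162 CPM (-1.01, SE 0.28), Apoo-ps (-1.58, SE 0.44) and the immediate early gene Egr1 (1.03, SE 0.34). All had adjusted p = 0.997. Htr3a (48899213 to 48911099) and Pts (50521617 to 50528724) lie on chromosome 9 on either side of Drd2. At EAE Htr3a was at 3.84 ± 1.28 in control and 1.55 ± 0.384 in cKO mice, and Pts at 29.0 ± 1.35 and 12.5 ± 2.20, with Pts passing there (-1.18, SE 0.15, adjusted p = 0.044) and Htr3a not (-1.27, SE 0.34, adjusted p = 0.0594) by the same test.

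None of 30 lists passed camera at basal, by fry or with an estimated correlation. Nearest were MHC class I (median 0.37), proliferation (0.83) and motor neurons (-0.40), each with a camera adjusted p of 0.0672. Gfap (-0.29, SE 0.26), Rgs5 (-0.37, SE 0.56) and Cryab (-0.40, SE 0.52) did not pass. The spread was the widest of the fits, with a biological coefficient of variation of 0.516 against 0.233 at EAE, and cKO basal 2 raised it. Without that library edgeR called 0 genes (388 unadjusted), the MHC class I median went to -0.11, and camera called myelin (-0.26), activated microglia (-0.28) and erythrocyte genes (-1.95) lower in cKO, with adjusted p = 0.838 with an estimated correlation. Without both control basal 1 and cKO basal 2, left out after the data were seen, it called 0 genes (892 unadjusted), while camera called 4 lists with small changes: myelin (-0.26), oligodendrocyte precursors (-0.24) and astrocyte markers (-0.14) lower, and immediate early genes (0.32) higher in cKO. Their adjusted p was 0.875 with an estimated correlation.

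The last comparison asked whether the EAE response differed between genotypes. By camera with its preset correlation, the rise of inflammatory lists and the fall of neuronal lists were smaller in cKO, while no single gene passed. With an estimated correlation no list passed (adjusted p of 0.202 to 0.515 for the lists that camera called). Without cKO basal 2 and cKO EAE 3, left out after the data were seen, the difference was -0.95 in place of -1.46 for the NF-kB response, -1.16 in place of -2.20 for MHC class I and 1.69 in place of 1.66 for motor neurons, and inflammatory cytokines were not called (camera adjusted p = 0.528). Motor neuron genes differed by a median of 1.66 on the log2 scale (cKO minus control, 8 of 10 higher adjusted over the list alone), with Slc5a7 at 2.74 (SE 0.69) and Slc18a3 at 2.67 (SE 0.84). The basal libraries themselves were apart on this list, at a mean log2 level of 4.98, 3.33 and 3.75 in cKO basal 1, 2 and 3 and of 4.48 to 4.78 in control basal, a spread about as large as the fall in control EAE (to 2.84 to 3.59). Neuronal genes differed by 0.84 (6 of 16 adjusted over the list alone), with Nefl at 1.46 (SE 0.38) and Nefh at 1.52 (SE 0.45), and astrocyte markers by 0.43, with Ntsr2 at 1.68 (SE 0.44). NF-kB genes differed by -1.46 (8 of 16 lower adjusted over the list alone), with Cd40 at -2.89 (SE 0.85) and Vcam1 at -1.47 (SE 0.46), and immediate early genes by -1.48, with Egr1 at -1.73 (SE 0.38) and Egr3 at -1.94 (SE 0.57). None of these genes passed singly, each with adjusted p = 0.547 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The lists had adjusted p of 0.205, 0.202, 0.205, 0.205 and 0.202 with an estimated correlation. Egr1 and Egr3 were also uneven at basal. Egr1 had 563, 775 and 952 counts in cKO basal 1, 2 and 3 and 435 to 476 in control basal. Egr3 had 67, 74 and 159 counts in the same cKO libraries and 67 to 100 in control basal. Part of both differences therefore came from the basal libraries.

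The genes with the smallest p were the potassium channel subunit Kcnab1 (1.42, SE 0.27), Hsd11b1 (1.60, SE 0.31), the glutamate receptor subunit Grin2c (1.52, SE 0.30), Etnppl (1.07, SE 0.21) and Nrp1 (-1.61, SE 0.32), also at 0.547. Etnppl, an astrocyte enzyme, fell from 66.6 ± 4.31 to 29.3 ± 2.22 CPM in control mice and was at 63.6 ± 6.96 and 58.7 ± 1.55 in cKO mice. Camera called 22 of 36 lists, 5 higher and 17 lower, and fry called 2, neurons and immediate early genes, at adjusted p = 0.0364. By edgeR 0 of 18601 genes passed (1697 at an unadjusted p below 0.05), while DESeq2 called 91 and limma voom with sample weights 2999. Without cKO basal 2 and cKO EAE 3, left out after the data were seen, edgeR called 0 genes (3438 unadjusted, smallest adjusted p 0.0911).

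The 3 cKO EAE mice differed in how far they had moved along the control response. Over 1937 genes that rose at least 2-fold in control mice, setting the control basal mean to 0 and the control EAE mean to 1, the median share was 0.569 in cKO EAE 1, 0.747 in cKO EAE 2 and 0.0634 in cKO EAE 3. It was 0.955 to 1.05 in the control EAE libraries and -0.0589 to 0.0242 in the cKO basal ones. Over 397 genes that fell at least 2-fold, the share was 0.304, 0.486 and 0.104 in cKO EAE 1, 2 and 3, and 0.875 to 1.12 in control EAE. The genes were chosen on the control EAE libraries, so a share near 1 there holds by construction.

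**Figure D3:**
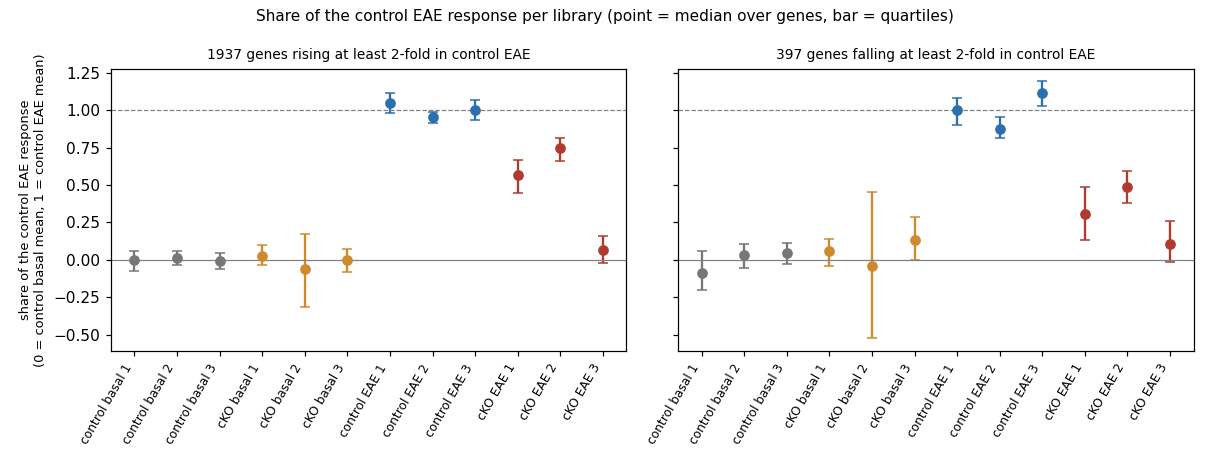
Share of the control EAE response in each of the 12 libraries over 1937 genes that rose and 397 genes that fell in control mice (points, medians; bars, quartiles; 0 is the control basal mean and 1 the control EAE mean on the log2 scale). The cKO EAE libraries lie at 0.569, 0.747 and 0.0634 for the rising genes and at 0.304, 0.486 and 0.104 for the falling genes.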

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

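The difference of the EAE response between genotypes (cKO minus control) passed camera for 22 gene lists, a test planned before the data were seen, and the groups' effects are listed here for that reason. Of the lists 0 passed with an estimated correlation and 2 by fry. Every test of a cause in this part was chosen after the result was seen, apart from the genotype as the cause of cKO basal 2.

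Infiltrating and inflammatory lists had a smaller rise in cKO. The median difference on the log2 scale was -3.01 for monocytes and infiltrating macrophages, -2.52 for proliferation, -2.37 for MHC class II, -2.20 for MHC class I, -2.13 for chemokines, -1.999 for the interferon gamma response, -1.65 for complement, -1.56 for T cells, -1.46 for the NF-kB response, -1.18 for the type I interferon response and -0.75 for inflammatory cytokines. In 5 of 16 T cell genes and 5 of 13 cytokines a group had 0 counts, so that the fitted differences of these genes depend on the prior count. With such genes at their bound, and those at a bound in both genotypes left out, the medians were -2.22 and -1.64, and with all such genes left out -2.04 and -1.32. Glial lists followed, with -1.54 for A2 astrocyte genes, -1.53 for A1 astrocyte genes, -1.39 for activated microglia and macrophages, -1.29 for pan-reactive astrocyte genes and -0.70 for homeostatic microglia, and immediate early genes stood at -1.48. Upward differences were 1.66 for motor neurons, 0.99 for Schwann cells, 0.84 for neurons, 0.49 for myelin and mature oligodendrocytes and 0.43 for astrocyte markers. The adjusted p of these lists ran from 0.202 to 0.515 with an estimated correlation.

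Without cKO basal 2 and cKO EAE 3, left out after the data were seen, the downward differences were smaller. Proliferation stood at -1.29, MHC class I at -1.16, chemokines at -1.10, T cells at -0.86, activated microglia and macrophages at -0.74 and A2 astrocyte genes at -0.71. MHC class II stood at -1.54, A1 astrocyte genes at -1.07, complement at -1.01, the NF-kB response at -0.95, immediate early genes at -0.94, the type I interferon response at -0.70 and homeostatic microglia at -0.37. Monocytes and infiltrating macrophages stood at -2.40, and inflammatory cytokines, at -0.51, were no longer called by camera (adjusted p = 0.528). The T cell and cytokine values are fitted ones, without bounds. Upward differences were larger for myelin (0.88) and Schwann cells (1.26), and camera also called cholesterol synthesis (0.35), erythrocytes (2.63) and heat shock (0.26), with adjusted p of 0.401, 0.375 and 0.564 with an estimated correlation.

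The first pattern weighed was cKO EAE 3, which lay near the basal libraries. Its Ddx3y level of 77.0 CPM speaks against a swap with a basal library of this series, all of which had 0 counts of that gene. Its neuron list lay at -0.0584 from the control basal libraries, which speaks against dilution by nerve root tissue. All 4 genes near Drd2 that separated the genotypes in the other 11 libraries had this library on the cKO side, which speaks against a control mouse under a cKO label. Its share of the control response was 0.0634, above the intact cKO basal libraries and far below the other EAE libraries, so an animal without EAE and an animal with a very small response could not be told apart.

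The second pattern was cKO basal 2, apart from the other basal libraries. The median log2 ratio of the shortest genes exceeded that of the longest genes by 1.55 (outer groups of 5 by length), more than in any other basal library, as loss of long transcripts would give. By the rank correlation with length control basal 1 had the stronger trend (-0.610 against -0.332), so that the measures rank these libraries differently. With 25 Hox genes at 1 CPM or more, a brain sample in place of spinal cord is unlikely. The other cKO basal libraries had at most 0.0247% of genes over 4-fold from the control basal mean, so the genotype alone does not account for it.

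The third pattern was the difference in sex between EAE and basal libraries. Sex alone would put every male library near a share of 1 of the control response. The highest share among the 3 male cKO EAE libraries was 0.747 for rising genes and 0.486 for falling genes. The genes were chosen on the control EAE libraries, which can lower the share in other libraries, so a highest share under 1 is weak evidence. In the male library cKO EAE 3 the shares were 0.0634 and 0.104, far below 1. A part played by sex in the size of single changes was not testable, since no EAE library was female and no basal library male.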

How the results depend on the processing

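Of 4650 values of named genes and lists under other settings, 3896 kept direction and side of the threshold, 394 were no longer past it, 325 came to pass it and 35 changed sign, none of these past the threshold. The cause was not tested except where fewer libraries or genes are named. With an estimated correlation 0 lists passed in the control, cKO, EAE and difference comparisons with all libraries, and 17, 17 and 0 in control mice, cKO mice and the difference without both doubted libraries, and fry called 0 at EAE and 2 for the difference. In control mice limma voom called 11120 genes, the 6 libraries alone 8149, and the fit without both doubted libraries 8673, with 1724 to 2073 when 1 library was left out. In cKO mice no filter on low counts gave 493, voom 3648, DESeq2 1239, the 6 libraries alone 0, the fit without both doubted libraries 2715, and leaving out 1 library 5 to 1075. At EAE 305 genes passed at 2-fold or more, voom called 5790, DESeq2 4131, the fit of all 12 libraries 0, and leaving out 1 library 0 to 3418. At basal DESeq2 called 1 gene. Lists numbered 1 without filter, 3 with the replicate block, 4 by voom and 4 without both control basal 1 and cKO basal 2. They numbered 0 to 3 when 1 library was left out. For the difference voom called 2999 genes and DESeq2 91.

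Of the values that changed sign at basal, Psmb10, Psmb8, Tapbp, Birc5 and the MHC class I list were positive with cKO basal 2 and negative without it. By voom they were Cryab in cKO mice (0.0411), Drd2 at EAE (-0.0831), Rgs5 (0.10), Psmb10 (-0.0517) and Birc5 (-0.17) at basal, and Drd2 (-0.52), Tnf (-2.45) and Il6 (-0.90) in the difference. Without control basal 1 and cKO basal 2 together, Rgs5 was at 0.13, Psmb10 at -0.0521 and Birc5 at -0.15 at basal. Without both doubted libraries Drd2 was at -0.21 and Gfap at 0.00612 in the difference. DESeq2 size factors and the DESeq2 test put Cryab at -0.0689 and -0.0690 in the difference. When 1 library was left out, the basal ranges were -0.659 to 0.0683 for Rgs5, -1.03 to 0.00799 for Cryab, -0.34 to 2.87 for Psmb10, -0.12 to 2.32 for Psmb8, -0.0601 to 0.999 for Tapbp, -0.43 to 2.05 for Birc5 and -0.11 to 0.59 for the MHC class I list. The ranges for the difference were -0.32 to 0.43 for Drd2, -0.37 to 0.63 for Cryab, -2.37 to 0.84 for Tnf, -0.25 to 2.24 for Il6 and -0.71 to 0.0755 for Gfap. Tnf and Il6 had 0 counts in every cKO basal library, so that their values and signs in the difference depend on the prior count.

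The replicate numbers were shared between groups without a stated pairing. Of 18 pairs of libraries with the same number 4 had a correlation over 0.1 (-0.458 to 0.371). With the replicate block 0 genes passed at EAE, 2509 in control and 5 in cKO mice, and Tnf in the difference was at -0.52. A fit with sex as a covariate was not run, since sex and state coincide. Depth limited genes with few counts. In a simulation at EAE edgeR recovered 32% of planted 2-fold and 81% of 4-fold changes, against 0% and 0% at basal. The planted genes had a mean of at least 1 CPM, so these values do not measure the limit set by depth. The simulated spread was the fitted one, with a biological coefficient of variation of 0.516 at basal and 0.233 at EAE.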

Other observations

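For some cell lists that camera did not call between genotypes at EAE the levels in each mouse are given here, without a test per mouse. They are mean log2 above basal, where basal is the 3 control libraries for control mice and cKO basal 1 and 3 for cKO mice, cKO basal 2 being left out after the data were seen. Fibroblast and meningeal genes lay above basal by 2.34, 1.54 and 0.85 in cKO EAE 1, 2 and 3 and by 1.64, 1.79 and 1.69 in the control EAE libraries. Neutrophil genes lay above basal by 2.97, 2.55 and 1.40 in cKO and by 2.66, 2.75 and 2.75 in control mice, and endothelial genes by 0.57, 0.58 and 0.35 and by 0.56, 0.49 and 0.67. On the same scale cKO basal 2 itself lay at 1.89 for neutrophil genes, above cKO EAE 3. Myelin genes, which camera did call at EAE (adjusted p = 0.498 with an estimated correlation), lay at 0.38, 0.23 and -0.10 in cKO EAE 1, 2 and 3 and at -0.52, -0.48 and -0.68 in control EAE.

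A single factor scaling every gene group was tested after the values were seen. It would lower the myelin list in cKO EAE 1 and 2 as in control mice, whereas the lower of both libraries stood at 0.233 above the intact cKO basal libraries. That test was not independent of the values that prompted it, and it rested on the baseline: the list's mean log2 level was 8.93 and 8.78 in cKO EAE 1 and 2, against 8.70 and 8.40 in cKO basal 1 and 3 and 8.81 to 8.82 in control basal. Whether 1 common factor accounts for the smaller response stayed open. Mice sampled at an earlier or a milder point of disease and mice protected by the deletion could both give it, and clinical scores were not given in the sources used here.

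Genes around Drd2 separated the genotypes. Htr3a and Pts were noticed first, as named genes of the basal comparison, and the test was written afterwards. Of 16435 genes at a mean of 1 CPM or more, 26 had all 6 cKO libraries on 1 side of all 6 control libraries. Of 94 genes within 5 Mb of the start of Drd2, 4 did so: Sik3 was higher in cKO (295 against 233 CPM at basal, 266 ± 8.59 against 212 ± 3.96 at EAE), and Nxpe4 (9.44 ± 1.52 against 15.3 ± 2.07, and 11.5 ± 1.07 against 24.6 ± 7.03), Htr3a and Pts were lower. Of 200 splits of the libraries within basal and EAE, 1 gave as many, the real one, and the highest other gave 2 (exact permutation p = 0.005). With Htr3a and Pts left out the exact permutation p was 0.01, and with library totals as scaling it was 0.01 with both genes and 0.08 without. An effect of the deletion on neighbouring genes and DNA of another strain linked to the targeted locus could each give this, and neither was tested.

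Other splits of the 3 + 3 libraries were fitted as a planned check. In control mice the real grouping gave 3183 genes and the highest other split 0, so that 1 of 10 splits gave as many. In cKO mice the real grouping gave 7, and 2 of 10 splits gave as many, the other one 391 after exchanging cKO basal 2 with cKO EAE 3. Between genotypes at EAE the real grouping gave 1374 and the highest other 0 (1 of 10). At basal and for the difference of responses the real count was 0. Every split then gives as many by construction (10 of 10 and 50 of 50), so these checks carry no information. The 50 were a random sample of the possible splits. With 10 splits the smallest share possible is 1 of 10, so the other checks could not exclude chance either.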
